A study of Mus musculus with 16 samples.

How the data were processed

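RNA was measured in 16 cultures of mouse neural progenitor cells grown from embryonic day 18.5 cortex, in 4 groups of 4 biological replicates. Per the labels' protocols, cells received a lentivirus carrying Cas9 with a guide RNA against Chd1 (the knockout, KO) or a control lentivirus with Cas9 alone (labelled wild type, WT), and were selected with puromycin for 48 h and expanded. WT cells and one set of KO cells were given DMSO. The other KO cells were given 10 nM dihydrotestosterone (DHT, an androgen) for 24 h, either alone or with 10 µM enzalutamide (ENZ, an androgen receptor antagonist) added 30 min earlier. Replicates came from embryos of 2 litters, and the labels do not say which replicate came from which litter. Per the labels' protocols, polyA RNA with an integrity number above 8 was sequenced as paired 150 bp reads, with 30 M reads (M, mega) sought per sample.

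Per the submitters' processing notes, reads were quantified with kallisto against GRCm39 (the versions are not stated). Per the file headers, each deposited file holds estimated counts per transcript, transcript length, effective length and TPM (transcript abundance scaled to a fixed library sum). The deposited estimated counts (expected counts) carry no normalization between samples. The deposited TPM values were not tested for differences between groups. They served as weights for each gene's transcript length and GC content, on which the length offset and the length and GC trends rest. They were also read for single Chd1 transcripts and a check of their sums. Each file lists 146190 transcripts, of which 135007 were matched by transcript identifier to 49166 genes of the GENCODE M21 annotation. That annotation is of another genome build, so it was used for names only and no coordinates are given. The matched transcripts held 98.85% to 99.12% of each library's estimated counts. Total estimated counts were 20.2 M in WT DMSO replicate 1 and 31.8 to 36.9 M in the other 15 libraries. Reads shared between paralogs or pseudogenes, such as those of ribosomal protein genes, were divided by kallisto's model, so values of near-identical genes are uncertain.

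Estimated counts were summed per gene, rounded and tested with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model of the 4 groups was fitted to all 16 libraries, with TMM normalization and the filterByExpr filter, which left 16971 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05 with no minimum fold. Fold changes are log2 values. Their standard error (SE) was computed as the absolute log2 fold change divided by the square root of edgeR's F statistic. Counts scaled by library size to a common megacount (CPM) and log2 CPM (prior count 2) were computed with the same normalization. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

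The labels do not state that replicate numbers pair the cultures, so this was checked on 9747 genes with a mean of at least 10 CPM. After each group's mean was removed, libraries with the same number correlated across genes at r = 0.16 to 0.79 in the 4 comparisons, all above the minimum of 0.1 set for calling them paired. Outside these comparisons, WT DMSO replicate 1 fell below that minimum, at -0.01 with KO DHT replicate 1 and 0.08 with KO DHT+ENZ replicate 1. Of the 16 libraries, 10 had their own number in the closest library of another group. KO DMSO replicate 1, for example, correlated at 0.79 with KO DHT replicate 4 and at 0.45 with KO DHT replicate 1. These correlations therefore could not tell pairing by number from a likeness of replicates 1 and 4. Low levels of Y-linked transcripts, given in the last paragraph, did set replicate 1 apart from replicate 4 in every group. The model without the replicate number is given first because it was planned so, although the minimum for pairing was met. The model with the replicate number as a block is given beside it where the 2 differ. The common biological coefficient of variation was 0.212 without the block and 0.122 with it.

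The comparisons were KO DMSO against WT DMSO, KO DHT against KO DMSO, KO DHT+ENZ against KO DHT, and KO DHT+ENZ against KO DMSO. There was no WT culture with DHT and no culture with ENZ alone. The design therefore cannot test whether the genotype changes the response to DHT, nor separate antagonism of DHT from other effects of ENZ. The comparisons, the model, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. Chd1 is always named. In each comparison the 10 largest rises and the 10 largest falls are named among called genes with a mean of at least 1 CPM, the same direction in all 4 same-numbered pairs and a symbol that is not a provisional one. Places left open were filled with the smallest p-values that passed in the blocked model, and with fewer than 5 in a direction the 5 smallest unadjusted p-values are named as not having passed. Results of some genes that this rule names are left out. From a described list, the 2 to 4 members with the smallest p-values are named.

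There were 31 gene lists, covering CHD remodellers and their elongation partners, chromatin regulators of Mendelian disorders, androgen receptor targets, steroid receptors and enzymes, cholesterol synthesis, cell cycle phases, neural cell types, other cell types that cortex could contribute, signalling and stress responses, ribosomes, respiration, matrix, synapse and sex-linked genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation and with fry. Of the 29 list calls made in the 4 comparisons, 2 held with an estimated correlation and the same number with fry. The DESeq2 1.42.0 Wald test, limma-voom with the replicate block as a random effect, DESeq2 size factors, no count filter, a transcript-length offset, a minimum fold of 1.5, the compared libraries alone and the omission of each library were the main alternatives.

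The relation between 2 effects across genes was taken as a slope with the shared group's libraries divided in all 6 ways so that no library served both effects, and was set against 20 simulations with no difference between any of the groups.

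The tests were run first on simulated data with 200 of 16971 genes changed. These were drawn from the real genes' means, library sizes, replicate effects and dispersions, as fitted with the replicate block. Replicate effects were thus built in, so a gain from the block was fixed in advance and does not show that the block suits the real data. Without the block, the share of changed genes found at a fold of 1.5 and 2 was 26% and 50% for KO against WT, 22% and 55% for DHT against DMSO, 30% and 62% for DHT+ENZ against DHT, and 24% and 57% for DHT+ENZ against DMSO, with 0 to 1 false calls. With the block these shares were 64% and 63%, 46% and 68%, 64% and 70%, and 53% and 70%. The false calls with the block were 5, 5, 14 and 6 in the same order, so DHT+ENZ against DHT had the most.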

Results

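Expression was measured by polyA RNA sequencing in 16 libraries from cultured mouse cortical progenitors, with 4 libraries in each of the groups WT DMSO, KO DMSO, KO DHT and KO DHT+ENZ. Depth ranged from 31.8 to 36.9 M estimated counts, except for WT DMSO replicate 1 with 20.2 M. The first principal component of log2 CPM held 36% of the variance and parted replicates 1 and 4 of every group from replicates 2 and 3. The second held 14.5% and parted WT DMSO replicate 1 from the other 15 libraries.

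**Figure D1:**
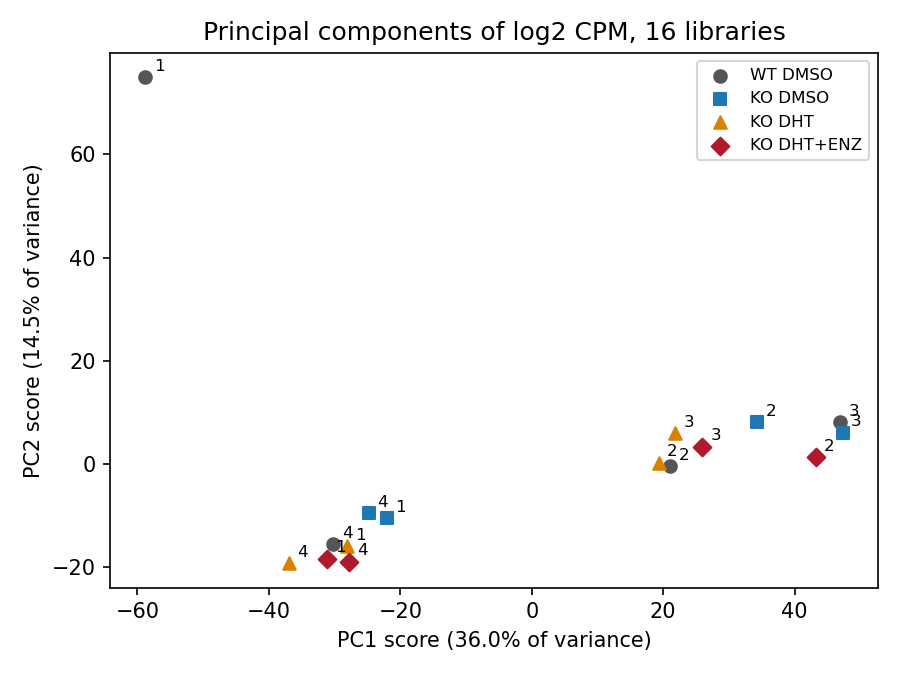
Scores of the 16 libraries on the first principal component (x axis, 36% of variance) and the second (y axis, 14.5%) of log2 CPM, with shape and colour for the group and the replicate number beside each point. Replicates 1 and 4 lie at scores below 0 on the x axis and replicates 2 and 3 above 0, and WT DMSO replicate 1 lies alone at 74.9 on the y axis.

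Chd1, which encodes a chromatin remodeller of transcribed genes, was measured at similar RNA levels in the knockout and control cultures. Its level was 66.7 ± 5.73 CPM in WT DMSO, 67.3 ± 2.68 in KO DMSO, 72.0 ± 3.87 in KO DHT and 68.2 ± 5.73 in KO DHT+ENZ (SD, n = 4 each). The log2 fold change of KO DMSO over WT DMSO was 0.01 (SE 0.08; adjusted p = 1, edgeR). Small insertions or deletions at a guide's cut site need not lower the RNA of a gene, so this level neither checks nor contradicts the genotype labels.

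The comparison of KO DMSO with WT DMSO asked how cultures given the Chd1 guide, labelled knockout, differed from control cultures without added androgen. No gene passed in the main edgeR model. The nearest to the threshold on the higher side were Ctsh, a lysosomal protease (0.39, SE 0.10), Hsdl2 (0.29, SE 0.08), Lalba (0.86, SE 0.25), Bves (0.28, SE 0.09) and Zfp27 (0.33, SE 0.10), as log2 fold changes with n = 4 per group. On the lower side they were Actn1, an actin crosslinker (-0.43, SE 0.11), Syde1 (-0.30, SE 0.08), Amotl2, which acts at cell junctions in Hippo signalling (-0.66, SE 0.18), Tmem170 (-6.39, SE 1.55) and Rn7s1 (-6.30, SE 1.75). None of these 10 passed (adjusted p = 1 for each, edgeR). The last 2 rested on WT DMSO replicate 1, where Tmem170 was at 983 CPM against 2.87 to 4.13 CPM in the other WT libraries. Without that library their log2 fold changes were -0.19 and 1.02.

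Of 31 lists 3 passed camera at the preset correlation, none of them with a called member. Genes of the integrated stress and unfolded protein responses were lower in KO DMSO, with a median log2 fold change of -0.16 over 32 measured genes (adjusted p = 6.67e-06, camera; adjusted p = 0.346 with an estimated correlation). Their smallest p-values belonged to the amino acid transporter genes Slc7a5 (-0.20) and Slc3a2 (-0.20) and the stress-response transcription factors Atf4 (-0.29) and Atf5 (-0.29). Extracellular matrix and collagen genes were lower, with a median of -0.15 over 35 genes (adjusted p = 2.71e-05, camera; adjusted p = 0.346 with an estimated correlation), among them Tnc (-0.39), Col5a1 (-0.33) and Col4a2 (-0.26). The 8 measured markers of pericytes, meninges and fibroblasts, of which the matrix list holds only Col1a1, had a median of -0.39 with 7 lower, and did not pass (adjusted p = 0.204, camera). Their means in pairs 1 to 4 were -0.61, -0.16, -0.22 and 0.03, beside -0.44, -0.24, -0.22 and 0.13 for the matrix list, so a different share of such cells was not excluded. Oxidative phosphorylation genes were higher, with a median of 0.07 over 44 genes (adjusted p = 0.00231, camera; adjusted p = 0.994 with an estimated correlation), including Ndufs1 (0.19) and Sdha (0.14). Adjusted over the list alone, 0 genes of each of these lists passed without the block, and with it 9 of the stress response list and 3 of the matrix list were lower.

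Of 16971 genes, 0 were changed in edgeR, with 508 at an unadjusted p under 0.05. The count was 0 with the replicate block (1329 at p under 0.05; smallest adjusted p = 0.475, edgeR), 0 in DESeq2, 9 in DESeq2 with the block and 0 in limma-voom with the block as a random effect. With WT DMSO replicate 1 left out and the block kept, a setting chosen after the data were seen, 3 genes passed in edgeR, each at adjusted p = 0.0312. These were Adamts1, a matrix protease (-0.58, SE 0.08), Bcar3 (0.52, SE 0.08) and Wnt7a, a Wnt ligand (0.45, SE 0.07), named after their values were seen.

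The comparison of KO DHT with KO DMSO asked how Chd1-targeted progenitors answered 24 h of androgen. Androgen left no gene past the threshold, and the androgen receptor target list did not move as a group. Of its 37 measured genes 0 changed, over all genes or adjusted over the list alone, the median log2 fold change was -0.02 and the mean 0.02, and the list did not pass (adjusted p = 0.567, camera). Zbtb16, a zinc finger transcription factor gene of that list that androgens and glucocorticoids are known to induce, came nearest. It was at 3.83 ± 0.292 CPM in KO DMSO and 6.06 ± 0.541 in KO DHT (SD, n = 4 each), higher in 4 of 4 pairs, and did not pass (log2 fold change 0.66, SE 0.23; adjusted p = 1, edgeR). Fkbp5, a widely used androgen receptor target, had a log2 fold change of 0.02 (SE 0.14).

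The other genes nearest to the threshold on the higher side were Magt1, a magnesium transporter gene (0.80, SE 0.25), Elk4 (0.24, SE 0.08), Nfia, a glial transcription factor gene (0.25, SE 0.09), and Itpr2 (0.22, SE 0.08). On the lower side they were Tram1l1 (-0.28, SE 0.09), Moap1 (-0.44, SE 0.14), Pyroxd1 (-0.30, SE 0.10), Nr1d1, a repressor of the circadian clock (-0.26, SE 0.09), and Taf9 (-0.56, SE 0.20). Each had adjusted p = 1 in edgeR. Chd1 had a log2 fold change of 0.10 (SE 0.08).

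Of 31 lists 8 passed camera at the preset correlation and none with an estimated correlation, where each had adjusted p = 0.746. Those lower with DHT were ribosomal proteins (median -0.10, 78 genes; Rpl10 -0.40, Rpl3 -0.25), oxidative phosphorylation (-0.10, 44 genes; Sdhc -0.16, Ndufb10 -0.31), cholesterol synthesis (-0.10, 26 genes; Mvd -0.24, Tm7sf2 -0.21) and G1/S and DNA replication (-0.09, 30 genes). Those higher were chromatin regulators of Mendelian disorders (0.12, 42 genes; Nsd1 0.23, Kmt2d 0.46), synapse and ion channels (0.09, 39 genes; Gria4 0.15, Grik1 0.43), steroid receptors and steroid enzymes (0.15, 18 genes) and the CHD family (0.12, 10 genes). Camera's adjusted p was 9.49e-06 for the ribosomal protein, oxidative phosphorylation and chromatin lists, 0.000141 for cholesterol synthesis, 0.00216 for synapse and 0.0384 for the other 3, and 0 members passed over all genes or adjusted over the list alone. Long transcripts were higher in KO DHT than in KO DMSO in the same libraries. The rank correlation of fold change with transcript length over 9747 genes was 0.10, 0.66, 0.53 and 0.41 in pairs 1 to 4, a relation across genes, which are not independent replicates.

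Of 16971 genes, 0 changed with DHT in edgeR (193 at an unadjusted p under 0.05). The counts were 0 with the replicate block (1358 at p under 0.05; smallest adjusted p = 0.606, edgeR), 0 in DESeq2 with and without the block, and 0 in limma-voom with the block as a random effect. On simulated data the edgeR model found 55% of genes changed by a fold of 2 and 22% of those changed by 1.5 in this comparison, so changes of that size in a few genes were not excluded.

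The comparison of KO DHT+ENZ with KO DHT asked what the androgen receptor antagonist did on top of androgen. Genes of mitosis fell in all 4 pairs, while the lysosomal protease gene Ctsl and the sugar-metabolism genes Uap1l1 and Renbp rose. Mki67, the proliferation marker Ki-67, went from 386 ± 33.8 CPM in KO DHT to 240 ± 14.3 in KO DHT+ENZ (SD, n = 4 each; log2 fold change -0.69, SE 0.10; adjusted p = 0.00752, edgeR). Top2a, the topoisomerase of dividing cells, went from 552 ± 55.7 to 355 ± 31.4 CPM (-0.64, SE 0.10; adjusted p = 0.0111, edgeR). Uap1l1, which encodes a relative of a nucleotide-sugar enzyme, rose from 29.9 ± 2.96 to 58.5 ± 5.37 CPM (0.97, SE 0.12; adjusted p = 0.00611, edgeR).

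Of 16971 genes, 45 changed in edgeR, 13 higher and 32 lower. Other genes among the largest falls encode proteins of mitosis, most of them motors or spindle and centromere proteins. These were Kif14 (-0.75), Aspm (-0.71), Kif15 (-0.69), Cenpf (-0.68), Cenpe (-0.65), Cdca2 (-0.65) and the spindle checkpoint kinase Ttk (-0.63), with the DNA helicase gene Pif1 (-0.91). Their adjusted p ran from 0.00752 for Kif14 and Cdca2 to 0.0469 for Aspm (edgeR). The largest rises included the lysosomal protease gene Ctsl (0.52; 135 ± 7.5 to 193 ± 18.1 CPM), Renbp, an enzyme of amino-sugar metabolism (0.84), Cystm1 (0.85), AI413582 (0.68), Parp3 (0.56) and the clock repressor Nr1d1 (0.48). Counts that kallisto assigned to the mitochondrial 12S ribosomal RNA gene mt-Rnr1 (0.63) and the mitochondrial tRNA gene mt-Tp (0.91) also rose in these polyA libraries. Whether the mature RNAs rose was not tested. Adjusted p for the rises ran from 0.00611 for Cystm1 and Uap1l1 to 0.0469 for Parp3 (edgeR). Mitochondrial genes held 4.31% to 4.5% of counts in the 4 KO DHT+ENZ libraries and 2.90% to 3.74% in the other KO libraries.

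**Figure D2:**
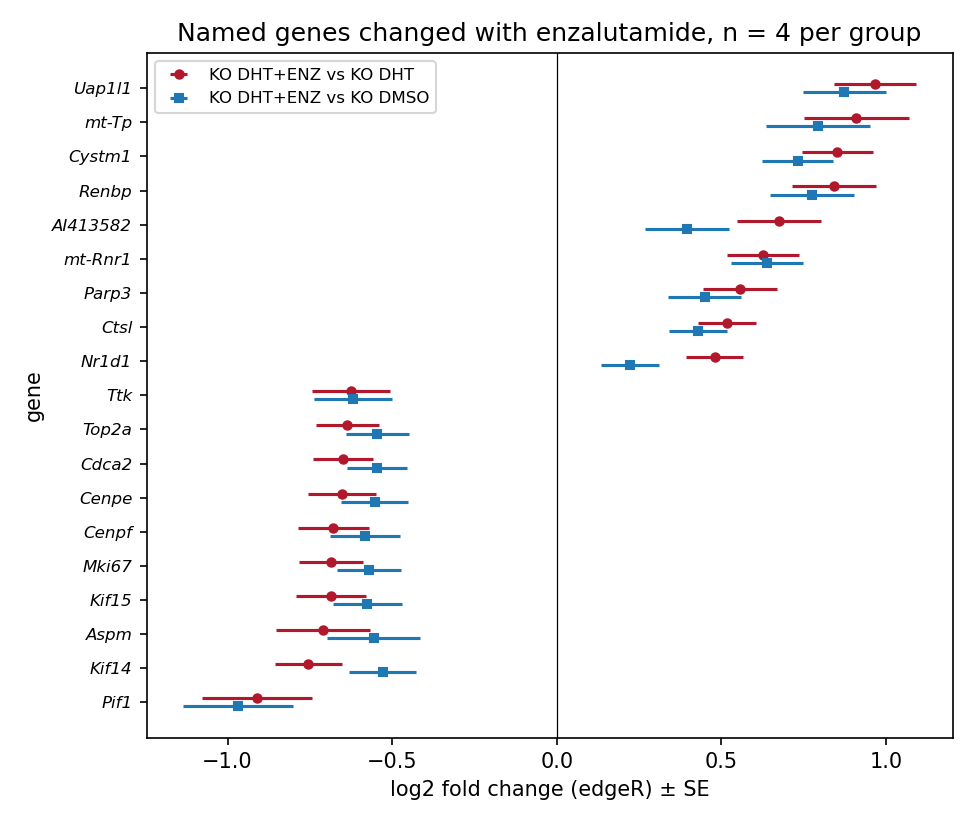
Log2 fold changes from edgeR (x axis, with SE bars) of 19 genes among the largest rises and falls in KO DHT+ENZ against KO DHT (y axis), in that comparison (red circles) and against KO DMSO (blue squares), n = 4 per group. Uap1l1 stands highest at 0.97 and Pif1 lowest at -0.91 against KO DHT, and every gene drawn has the same sign against KO DMSO.

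The list of G2/M and mitosis genes was lower as a group. Of its 32 measured genes 9 fell over all genes tested, 32 adjusted over the list alone, and 31 with the replicate block. The median log2 fold change was -0.52 (adjusted p = 3.63e-46, camera; adjusted p = 0.0248 with an estimated correlation), and the list means in pairs 1 to 4 were -0.58, -0.50, -0.50 and -0.49. With WT DMSO replicate 1 left out and the block kept, a setting chosen after the data were seen, adjusted p was 0.101 with an estimated correlation. Genes of G1/S and DNA replication had a median of -0.31 over 30 genes, with 0 changed over all genes and 0 adjusted over the list alone (adjusted p = 8.63e-10, camera; adjusted p = 0.53 with an estimated correlation). With the replicate block 14 of them fell, including the ribonucleotide reductase genes Rrm1 (-0.37) and Rrm2 (-0.37) and the checkpoint gene Clspn (-0.51). Among 30 progenitor markers 1 fell, Mki67, which the mitosis list also holds, and the median of that list was -0.03.

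**Figure D3:**
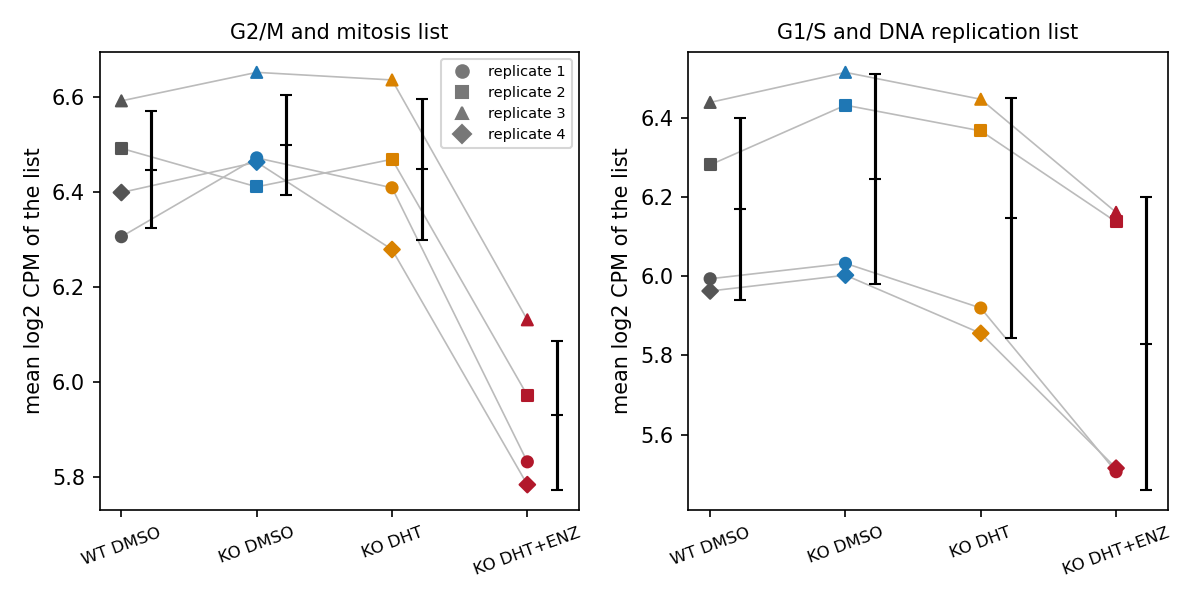
Mean log2 CPM (y axis) of the G2/M and mitosis list (left) and the G1/S and DNA replication list (right) in each library by group (x axis), with lines joining libraries of one replicate number and black bars for the group mean and SD, n = 4. In each replicate number the KO DHT+ENZ library is the lowest of the 4 on both lists.

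Another 8 lists passed camera in this comparison, all of them lost with an estimated correlation. Ribosomal proteins had a median of 0.23 (78 genes; adjusted p = 0.53 with an estimated correlation) and oxidative phosphorylation 0.21 (44 genes; adjusted p = 0.50 with an estimated correlation). With the replicate block 10 ribosomal protein genes rose, among them Rpl31 (0.33) and Rps23 (0.28), as did 3 respiratory chain genes, Sdhc (0.30), Uqcrc2 (0.24) and Cox5b (0.33). In replicate 1 these lists' mean changes were -0.02 and 0.00, against 0.19 to 0.39 in the other pairs. Short transcripts were higher in the same 3 pairs, with a rank correlation of fold change with transcript length of 0.20, -0.59, -0.30 and -0.35 in pairs 1 to 4 across genes, which are not independent replicates. After a correction of each library for its trend on transcript length, a setting chosen after the data were seen, 4 ribosomal protein and 3 respiratory chain genes were called with the block, and the blocked medians went from 0.22 to 0.14 for ribosomal proteins, from 0.20 to 0.13 for oxidative phosphorylation and from -0.13 to -0.05 for chromatin regulators, so part of these changes went with transcript length. The integrated stress and unfolded protein response list had a median of 0.18 (32 genes; adjusted p = 0.146 with an estimated correlation), with 2 genes higher adjusted over the list alone and 3 with the block, which were Atf5 (0.51), Ddit3 (0.65) and Aldh1l2 (0.40). Immediate early genes had a median of 0.12 (33 genes; adjusted p = 0.146 with an estimated correlation), with 1 higher adjusted over the list alone and Nr4a1 (0.60), Nr4a3 (0.62) and Klf4 (0.50) higher with the block. Cholesterol synthesis had a median of 0.13 (26 genes; adjusted p = 0.53 with an estimated correlation), the xenobiotic and NRF2 response 0.10 (23 genes; adjusted p = 0.53 with an estimated correlation), BMP and TGF-beta targets 0.14 (18 genes; adjusted p = 0.354 with an estimated correlation) and chromatin regulators -0.12 (42 genes; adjusted p = 0.53 with an estimated correlation). The androgen receptor target list had a median of 0.05 and did not pass (adjusted p = 0.55, camera). Of its members Fkbp5 fell with the block (-0.29, SE 0.07; adjusted p = 0.0271, edgeR; 0.728 without the block). Zbtb16 was lower in 4 of 4 pairs without passing (-0.49, SE 0.23; adjusted p = 0.717, edgeR).

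With the replicate block edgeR called 591 genes, 266 higher and 325 lower, including all 45 called without it. DESeq2 without the block called 211, and limma-voom with the block as a random effect called 407. Leaving out KO DHT replicate 1, 2, 3 or 4 left 14, 13, 11 or 25 genes in edgeR, leaving out KO DHT+ENZ replicate 1, 2, 3 or 4 left 16, 2 (Uap1l1 and Cystm1), 28 or 9, and leaving out WT DMSO replicate 1, which is in neither group, gave 116. With only replicates 1 and 4 and the block 0 genes passed, and with only replicates 2 and 3, 655 did, a division chosen after the data were seen.

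The comparison of KO DHT+ENZ with KO DMSO set antagonist plus androgen against vehicle. Mitosis genes fell below the vehicle level as well, and Uap1l1, Renbp and the lysosomal enzyme gene Gaa rose above it. Cenpa, the centromeric histone, was at 93.2 ± 11.2 CPM in KO DMSO and 57.8 ± 8.77 in KO DHT+ENZ (SD, n = 4 each; log2 fold change -0.69, SE 0.12; adjusted p = 0.0287, edgeR). Ccnb1, the mitotic cyclin B1, went from 167 ± 13.8 to 108 ± 16.6 CPM (-0.63, SE 0.12; adjusted p = 0.0467, edgeR). Uap1l1 rose from 31.9 ± 3.24 to 58.5 ± 5.37 CPM (0.87, SE 0.12; adjusted p = 0.0215, edgeR).

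Of 16971 genes, 43 changed in edgeR, 9 higher and 34 lower. The falls included the spindle and kinetochore genes Knstrn (-0.70), Kif20a (-0.69), Bub1b (-0.62), Ttk (-0.62), Kifc1 (-0.62) and Tpx2 (-0.61), with Pif1 (-0.97) and the cell-surface gene Mdga1 (-0.77). The rises included the acid alpha-glucosidase gene Gaa (0.39), Rragd, a GTPase that signals amino acids at the lysosome (0.53), Tom1, of endosomal sorting (0.42), Renbp (0.78), Cystm1 (0.73), Bhlhe40, a clock and stress transcription factor (0.44), mt-Tp (0.79) and mt-Rnr1 (0.64). Abca1, the cholesterol exporter, rose from 93.0 ± 13.1 to 173 ± 23.4 CPM in the blocked model (0.89, SE 0.10; adjusted p = 0.000353, edgeR) and did not pass without the block (adjusted p = 0.0543, edgeR).

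The G2/M and mitosis list had a median of -0.58 over 32 genes (adjusted p = 8.58e-58, camera; adjusted p = 0.0099 with an estimated correlation). Of its genes 11 fell over all genes tested, 32 adjusted over the list alone and 31 with the block, and its means in pairs 1 to 4 were -0.64, -0.44, -0.52 and -0.68. With WT DMSO replicate 1 left out and the block kept, adjusted p was 0.0657 with an estimated correlation. G1/S genes had a median of -0.42 over 30 genes, with 0 changed over all genes and 0 adjusted over the list alone (adjusted p = 8.71e-17, camera; adjusted p = 0.387 with an estimated correlation). With the block 22 of them fell, including Rrm1 (-0.51), Rrm2 (-0.50) and Mcm6 (-0.39), and the blocked list had adjusted p = 0.0315 with an estimated correlation (0.12 with WT DMSO replicate 1 left out, 0.0344 after the length correction and 0.093 after a like correction for GC content). Another 6 lists passed at the preset correlation alone. These were the integrated stress and unfolded protein response (0.16; adjusted p = 0.359 with an estimated correlation), oxidative phosphorylation (0.11; adjusted p = 0.826), ribosomal proteins (0.12; adjusted p = 0.87), immediate early genes (0.13; adjusted p = 0.387), p53 targets (-0.08; adjusted p = 0.685) and oligodendrocyte lineage markers (-0.16; adjusted p = 0.359), each second value with an estimated correlation. The p53 targets that fell with the block were Gtse1 (-0.47) and Ckap2 (-0.48), both known for roles in mitosis.

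With the block edgeR called 499 genes, 145 higher and 354 lower, including all 43 called without it. DESeq2 without the block called 180, and limma-voom with the block as a random effect called 344. In edgeR 0 genes passed without KO DHT+ENZ replicate 1, 2 or 4, without KO DMSO replicate 1, 3 or 4, or with only the 8 compared libraries fitted; 22 passed without KO DMSO replicate 2, 47 without KO DHT+ENZ replicate 3 and 98 without WT DMSO replicate 1.

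The remaining 15 lists passed camera without the block in none of the 4 comparisons. With the block 3 of them passed at the preset correlation, which were astrocyte markers (higher; adjusted p = 0.0138, camera) and ribosome biogenesis (lower; adjusted p = 0.0297) in KO DMSO against WT DMSO, and hypoxia and glycolysis (higher; adjusted p = 0.0303) in KO DHT+ENZ against KO DHT. None of the 3 did with an estimated correlation (adjusted p = 0.702, 0.702 and 0.501). Among the 15, for KO DHT+ENZ against KO DHT, medians were -0.03 for elongation partners of CHD1 (28 genes), -0.05 for Wnt targets (20), -0.03 for astrocyte markers (18), -0.05 for neuronal differentiation (27), 0.09 for hypoxia and glycolysis (29), -0.09 for interferon response (29), 0.01 for ribosome biogenesis (38) and -0.04 for sex-linked genes (9). Markers of cells that cortex could contribute were few: 11 endothelial (-0.23), 6 microglial (-0.09), 8 pericyte and fibroblast (0.08), 8 ependymal (-0.03) and 1 erythroid gene (-0.02) were measured. The smallest camera adjusted p of the 15 without the block was 0.0791, for astrocyte markers and for ribosome biogenesis in KO DMSO against WT DMSO.

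Whether DHT reversed the knockout's effect, or ENZ that of DHT, was examined as a slope across genes with no library shared. The slope of the DHT effect on the knockout effect was 0.09 (-0.03 to 0.45 over 6 divisions), where simulations with no difference between any groups gave 0.17. With the block it was -0.03, against a simulated 0.00. The slope of the ENZ effect on the DHT effect was 0.04 (-0.10 to 0.28; simulated 0.17) and -0.07 with the block (-0.15 to 0.00; simulated 0.00). Fold changes that share the middle group gave -0.37 and -0.52, and the same simulations gave -0.50 for both. The simulated values are means of 20 simulations without a spread, and the 6 divisions reuse the same libraries. The slopes therefore could not decide whether either effect was reversed.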

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

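Among the tests below, those of depth and of genomic DNA for WT DMSO replicate 1, and every correction for GC content or transcript length, were chosen after the data had been seen; the counts over other divisions of the samples were planned. A value was singled out when it stood apart from the other 3 of its group with a Dixon ratio above its critical value, which chance gives in about 5% of groups of 4. Of 356 such tests (89 measures in 4 groups) 21 met it, which is near the share that chance gives. Of these, 6 were in WT DMSO replicate 1 and 15 in other libraries.

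WT DMSO replicate 1 stood apart from the other 15 libraries. It had 20.2 M estimated counts, 1.35% of counts on mitochondrial genes, 983 CPM of Tmem170 and 441 CPM of Rn7s1, and 569 genes lay more than 2 times above or below every other library, against 54 at most in any other. Kif15 at 42.6 CPM and Ttk at 21.2 CPM were low only among the WT DMSO libraries (57.9 to 60.2 and 30.8 to 32.1 CPM in the others), since the KO DHT+ENZ libraries were near these levels. Depth did not account for the genes beyond every other library, since 481 were left after all libraries were thinned to its total (51 at most elsewhere). GC content alone did not account for them either, since 600 were left after a GC correction (46 at most elsewhere). Before any correction, the rank correlation of its level with GC content over 9747 genes was 0.72, against -0.50 to 0.26 in the other libraries. A count of single outlying genes cannot say how far a broad GC shift sets this library apart. Genomic DNA may have added to the 430 genes above, because olfactory and vomeronasal receptor genes held 695.5 counts per megacount against 355.5 at most elsewhere, but it would lower all other genes by one factor and so does not explain the 139 genes below (52 at most elsewhere). No biological explanation was tested, and the source of the genes below stays open.

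The lower ribosomal protein and oxidative phosphorylation genes and the higher chromatin regulator genes in KO DHT went with a trend toward long transcripts in the same libraries. With the replicate block, all 3 of these lists still passed camera at the preset correlation after a correction of each library for transcript length, and 3 after a correction for GC content. At that correlation other divisions of these libraries that part all 4 pairs called up to 9 lists, against 7 for the real one. Passing at it therefore cannot decide whether either trend is the whole source. The length correction took the blocked medians of all 3 nearer to 0. They went from -0.11 to -0.07 for ribosomal proteins, from -0.10 to -0.06 for oxidative phosphorylation and from 0.14 to 0.03 for the chromatin list. After it the chromatin list's adjusted p was 0.0487 (camera), near the threshold. The length trend also stays open for the higher CHD family, whose blocked adjusted p went from 0.0079 to 0.126 (camera, median 0.12 to 0.06). The same holds for the steroid receptor and enzyme list, at 0.0576 before and 0.162 after (camera, median 0.15 to 0.05). With an estimated correlation none passed, before or after. A response to DHT therefore stays open as a hypothesis, as does a shift that follows the culture.

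The lower mitosis genes in KO DHT+ENZ were still there after both corrections. With the replicate block, 31 of 32 list members were called lower after the length correction and 31 after the GC correction, which argues against both trends. A cell cycle response to ENZ is a candidate explanation, and the design cannot say whether it passes through the androgen receptor, since no culture received ENZ alone. DHT alone had not raised the mitosis list, whose means over KO DMSO were -0.06, 0.06, -0.02 and -0.18 in pairs 1 to 4. With DHT+ENZ its means over KO DMSO were -0.64, -0.44, -0.52 and -0.68. These values argue against the fall being only the return of a rise caused by added DHT. A difference in culture density or harvest between wells was not recorded in the labels and stays open.

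Single values in other libraries also stood apart from the rest of their group. They were no more than chance would give over so many tests and were not weighed further. Mitochondrial genes held 4.5% of counts in KO DHT+ENZ replicate 3 (4.31% to 4.34% in the others). Mki67 was at 219 CPM in KO DHT+ENZ replicate 2 (247 to 248) and Cenpe at 41.7 CPM in the same library (51.3 to 53.2). Abca1 was at 138 CPM in KO DHT+ENZ replicate 1 (182 to 188), and Rn7s1 at 6.31 CPM in KO DHT+ENZ replicate 3 (0.683 to 1.41). Ccnb1 was at 188 CPM in KO DMSO replicate 3 (159 to 163), while Bub1b at 67.0 CPM (80.2 to 82.6) and Bves at 22.2 CPM (24.5 to 24.6) were low in KO DMSO replicate 2. Zfp27 was at 13.6 CPM in WT DMSO replicate 4 (12.9 to 13.0), Taf9 at 6.5 CPM in KO DHT replicate 4 (9.17 to 9.44) and Rragd at 40.1 CPM in KO DHT replicate 3 (44.2 to 44.9). As list means in log2 CPM, astrocyte markers were at 5.45 in WT DMSO replicate 2 and 5.98 in KO DMSO replicate 3, interferon response genes at 1.29 in WT DMSO replicate 3 and endothelial markers at 0.13 in KO DMSO replicate 2.

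Each comparison's 8 libraries can be divided into equal groups in 35 ways. Without the block, 2 of 35 divisions gave as many genes as KO DHT+ENZ against KO DHT (48 with these 8 libraries alone; 6183 at most elsewhere), so chance could not be excluded there. The other comparisons called 0 genes with their 8 libraries alone (for DHT+ENZ against DMSO 43 with all 16 fitted). Any division reaches 0, so the 35 of 35 that did say nothing about chance (at most 4159 for KO against WT, 6452 for DHT against DMSO and 7366 for DHT+ENZ against DMSO). For lists the real counts were 4, 6, 12 and 8 in the order of the report, reached by 27, 22, 3 and 15 of the divisions (14, 11, 14 and 11 at most elsewhere), so chance could not be excluded for them without the block. The highest gene count in every comparison came from dividing replicates 1 and 4 from replicates 2 and 3, a structure of the samples that the block removes. Among the 8 divisions that part all 4 pairs, the blocked model called 1155 genes for KO DHT+ENZ against KO DHT (0 at most elsewhere), 1917 against KO DMSO (1 at most elsewhere), 5 for DHT against DMSO (5 elsewhere) and 0 for KO against WT (0 elsewhere). For lists the blocked counts were 6 for KO against WT (8 at most elsewhere), 7 for DHT against DMSO (9), 11 for DHT+ENZ against DHT (11) and 9 for DHT+ENZ against DMSO (7), and without the block 5, 3, 1 and 1 of the 8 divisions gave as many lists. With 8 divisions no share can be under 12.5%.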

How the results depend on the processing

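The fits without WT DMSO replicate 1 in the block, with the knockout groups alone, with chosen replicate numbers and with length or GC corrections were chosen after the data had been seen. Named genes had 38 calls, where a gene called in both DHT+ENZ comparisons counts in each. All 38 calls held with the replicate block, with and without DESeq2, and in the DESeq2 Wald test. With DESeq2 size factors 29 held, with no count filter 22 and with a length offset 12. When each compared library was left out in turn, the calls were kept in 100 of the resulting values and lost in 204. None of the calls changed direction under any of these. Except where a setting itself uses fewer libraries or a stricter threshold, the cause of a change was not tested.

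For KO against WT the gene count of 0 became 1 with the length offset (Atp8a2) and 9 with DESeq2 and the block. In the blocked model it became 3 without WT DMSO replicate 1 and 176 with only replicates 2 and 3. For DHT against DMSO the blocked count became 1 without WT DMSO replicate 1 (the pseudogene Rps12-ps3), 1 with the knockout groups alone (the predicted gene Gm43118) and 2 with only replicates 2 and 3 (Magt1 and Rps12-ps3). These genes were named after their values were seen.

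For DHT+ENZ against DHT, and in the same order against DMSO, the counts of 45 and 43 genes became 211 and 180 with the DESeq2 Wald test, 17 and 9 with no count filter, 12 and 10 with the length offset, 591 and 499 with the block, 1031 and 820 with DESeq2 and the block, 407 and 344 with limma-voom with the block as a random effect, and 21 and 17 with a fold of at least 1.5. Against DMSO 0 passed with only the 8 libraries compared. With one library left out the ranges were 2 to 116 and 0 to 98. The blocked counts became 1480 and 1247 without WT DMSO replicate 1, 1798 and 1470 with the knockout groups alone, 0 and 0 with only replicates 1 and 4, and 1066 and 905 with the GC correction. Against DMSO only replicates 2 and 3 gave 278. Leaving out replicate 1, 2, 3 or 4 from the blocked model gave 1192, 112, 78 or 48 genes against DHT and 622, 222, 152 or 59 against DMSO.

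List counts of 3, 8, 10 and 8, in the order of the report, became 0, 0, 1 and 1 with an estimated correlation, with fry and with fry's mixed test. For KO against WT the 3 lists became 7 with the block, 10 with WT DMSO replicate 1 also left out, 7 with the block and length correction and 8 with the block and GC correction. The slope of the ENZ effect on the DHT effect went from 0.04 to -0.19 over genes with p under 0.01 in the libraries on the x axis. Over genes with a mean of at least 10 CPM the slope of DHT on knockout was 0.23 (0.05 to 0.81) and that of ENZ on DHT 0.05 (-0.33 to 0.40). With one replicate number left out the slopes ran from 0.10 to 0.15 for DHT on knockout and from 0.04 to 0.10 for ENZ on DHT.

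Signs that reversed belonged to values near 0 or to 1 library. With single libraries left out Chd1 in KO against WT ran from -0.03 to 0.06, Chd1 in DHT+ENZ against DMSO from -0.01 to 0.08 (-0.06 with the length offset), and Rn7s1, KO DMSO vs WT DMSO, from -6.71 to 1.02. Depth was 20.2 M in 1 library and at least 31.8 M in the others, which limits genes of a few CPM most.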

Other observations

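The tests of lysosome genes and the genes named here were chosen after values had been seen. In edgeR Apoe, Abca1 and Srebf1 were called higher with ENZ with the block and not without it, and no list of lipid transport genes was tested. Apoe, a lipid carrier, was at 96.7 ± 36.5 CPM in KO DHT and 174 ± 52.7 in KO DHT+ENZ (SD, n = 4 each), with a blocked log2 fold change of 0.87 (SE 0.13; adjusted p = 0.00302, edgeR), higher in 4 of 4 pairs. Abca1, the cholesterol exporter, changed by 0.65 (SE 0.10; adjusted p = 0.00302, edgeR) and Srebf1, a regulator of lipid synthesis, by 0.53 (SE 0.11; adjusted p = 0.0149, edgeR), each in 4 of 4 pairs. Without the block their adjusted p-values were 0.327, 0.268 and 0.759 (edgeR). Srebf2, the regulator of cholesterol synthesis, had a blocked change of 0.12 (SE 0.09; adjusted p = 0.596, edgeR).

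A rise of lysosome genes as a set with ENZ was put forward as a hypothesis after Ctsl and 9 other lysosome genes had been seen. A list of 46 lysosome genes was written, of which 36 had not been looked at. In the blocked model those 36 were higher in KO DHT+ENZ than in KO DHT (p = 0.00433, camera with an estimated correlation), with a median log2 fold change of 0.18, 31 of 36 above 0 and means of 0.16, 0.21, 0.07 and 0.20 in pairs 1 to 4. Of the 36, 6 were called higher in the blocked model, among them Ctsa, Ctsd, Tpp1, Atp6ap1 and Arsa, at 0.25 to 0.38, and 0 were called without it (edgeR). Camera's p was 0.0131 with WT DMSO replicate 1 left out, 0.00395 after the length correction and 0.0139 after the GC correction, and against KO DMSO it was 0.0285 (0.0563 with WT DMSO replicate 1 left out, 0.0197 after the length correction and 0.0507 after the GC correction). In KO DMSO against WT DMSO the 36 genes were also on the higher side (p = 0.0404, limma camera with an estimated correlation), with p = 0.102 when WT DMSO replicate 1 was left out, 0.0516 after the length correction and 0.0349 after the GC correction. In KO DHT against KO DMSO they were on the lower side without passing (p = 0.0921, limma camera with an estimated correlation; median -0.07, 8 of 36 above 0, means of -0.08, -0.04, -0.06 and -0.07 in pairs 1 to 4), so a lower level in KO DHT may be part of the rise read against it. The values are consistent with a broad but small rise of lysosome genes with ENZ, which a measure of lysosomes in these cells could test.

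Sex-linked transcripts were read in every library as a check that equal replicate numbers match. Xist was at 540 to 1710 CPM in all 16 libraries. Ddx3y, which lies on the Y chromosome, was at 1.38 to 1.81 CPM in the 4 libraries of replicate 1 and at 0.03 to 0.52 CPM in the other 12. The Y-linked Kdm5d (1.7 to 2.1 against 0.43 to 1.2 CPM), Eif2s3y (0.47 to 1.6 against 0 to 0.21) and Uty (0.38 to 1.1 against 0 to 0.36) were also higher in replicate 1. At these low levels they set replicate 1 apart in all 4 groups, WT DMSO replicate 1 included. Replicates 2 and 3 overlapped in each of these genes, so those numbers were not told apart. The labels give no sex for the cultures.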
